A study of Mus musculus with 18 samples.

How the data were processed

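RNA sequencing had been done on 18 libraries of mouse CD8+ T cells, 8 labelled naive, 8 labelled control and 2 labelled Tra2b knockout. Per the labels, RNA was purified with a micro-scale column kit and copied with a polyA-based low-input kit. The deposited files hold estimated counts per gene and estimated counts per transcript, written as whole numbers, and the gene values are sums of the transcript values. Per the submitters' processing notes, STAR 2.7.1a, SAMtools 1.9, StringTie 2.1.0, R 4.0.5 and DESeq2 1.30.1 were used, with the builds mm39 and mm10 named without their role. All 55536 Ensembl gene identifiers of the files are in GENCODE M21, so coordinates are given in GRCm38. The 18 columns were matched to the labels with 0 left over, and total counts per library ran from 68249844 to 93972513.

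Rows with numeric identifiers (26248 of 81881, holding 0.0513 to 0.132% of the counts) were left out because they name no gene. The 97 spike-in rows hold no counts. Genes were filtered with filterByExpr (minimum count 10) and scaled by TMM within each comparison, and levels are TMM-scaled CPM. Groups were compared with edgeR 4.0.16 (robust quasi-likelihood test, prior count 2) in R 4.3.3 for control against naive, knockout against control and knockout against naive. P-values were adjusted by Benjamini-Hochberg and called under 0.05. SE is the error of the log2 fold change and SD the spread between libraries.

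A set of 37 gene lists, 10 of them markers of other cells, was fixed before the data were examined, and 1 list gene (Ahsp) was not matched. Lists with 3 or more measured genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Every list was also adjusted over the list alone. Named genes were chosen by a rule set before the data were examined: Tra2b, then the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 4. For these, both knockout libraries had to lie on the same side of the control mean, or the naive and control groups not to overlap. Predicted genes, pseudogenes, receptor segments and rows without a symbol were excluded. Up to 4 measured members of each list with the smallest p were added. For transcript usage the rule named Tra2b, the TRA2B target list and the 8 genes with the smallest adjusted p. Receptor segments and single markers were examined as measures of library make-up.

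Transcript usage was tested with diffSpliceDGE and a Simes test per gene. Shares of Tra2b transcripts and measures of library make-up were compared with exact two-sided permutation tests of the difference in means. The smallest p is 0.000155 for 8 against 8 libraries and 0.0222 for 2 against 8. Intervals and limits from counts of 0 (3 counts) cover counting error only. For the reversal of changes, the controls were split 4 and 4 in 70 ways so that no library entered both differences.

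The steps were tested on simulated data with the design of each comparison. The gene test recovered 91.0, 98.5 and 100% of 1.5-, 2- and 4-fold changes for control against naive with 5 false calls, and 59.7, 97.0 and 100% for knockout against control with 11. A trend on gene length added to simulated knockout libraries gave 2809 false calls without a correction and 11 with it. The usage test recovered 64.5% of 4-fold changes in transcripts of at least 1 CPM for control against naive with 57 false calls, and 3.5% for knockout against control with 29.

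Alternatives set before the data were examined were DESeq2 1.42.0, RLE factors, total counts only, no low-count filter, a mean log2 CPM of at least 4, all groups in one fit, an absolute log2 fold change of at least 1, the replicate number as a block, limma voom with sample quality weights, thinned libraries, and leaving out each library. Lists were also tested with an estimated correlation and fry, usage with voom and with a minimum of 10 counts, and the reversal with all controls in both differences. The alternatives chosen after seeing the data were controls 1 and 2 alone, controls 3 to 8 alone, removal of a trend on exon length and GC content, the control against naive test without receptor segments and other-cell lists, and a quasi-likelihood fit for transcript usage. Replicate numbers were not used as pairs. Over 20651 genes, residuals of control and naive libraries with the same number had correlations between -0.026 and 0.032, and 1 of 8 was highest with its own number. For control and knockout libraries they were 0.01 and 0.05, and a pair with different numbers reached 0.063. There 2 of 2 were highest with their own number, which is no evidence of pairs, since the residuals of 2 knockout libraries mirror each other.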

Results

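Gene and transcript counts were examined in 18 RNA sequencing libraries of mouse CD8+ T cells from spleen and lymph nodes. The labels give the genotype as OT-I, a transgenic line whose T cell receptor recognises the ovalbumin peptide SIINFEKL. The libraries fell into 8 labelled naive at day 0, 8 labelled control, from cells that received a scrambled sequence, and 2 labelled Tra2b knockout. The control and knockout cells were taken at day 4 after stimulation with SIINFEKL and antibodies to the costimulatory receptors OX40 and 4-1BB. Total counts per library ran from 68249844 to 86932452 in the naive libraries and from 73735681 to 93972513 in the controls. They were 79197461 and 93495846 in the knockout libraries. The labels do not say whether libraries of one group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

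Tra2b encodes a splicing regulator that binds its own transcript, and the series' title concerns an ultraconserved poison exon of this gene, an exon that carries stop codons. The gene (ENSMUSG00000022858.16) lies on the minus strand of chromosome 16, from 22244549 to 22266005 in GRCm38. Tra2b stood at 290 ± 28.7 CPM in the libraries labelled naive and 467 ± 59.6 CPM in the controls (SD, n = 8 each). It was 1.61-fold higher in the controls (log2 fold change 0.69, SE 0.08, adjusted p = 4.15e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The naive libraries also differed in receptor segments and markers of other cells, described below, so this difference cannot be assigned to stimulation. Scaled over all 18 libraries, single values ran from 249 to 352 CPM in the naive libraries and from 335 to 527 CPM in the controls, and the knockout libraries stood at 358 and 371 CPM. In the comparison of knockout with control, 357 ± 2.68 CPM (SD, n = 2) against 452 ± 56.3 CPM (SD, n = 8) gave a log2 fold change of -0.34 (SE 0.13, adjusted p = 0.0899, same test), which did not pass. It passed without control 2, at -0.40 (adjusted p = 0.00803, same test), and, in alternatives chosen after seeing the data, against controls 3 to 8, at -0.37 (adjusted p = 0.00901), and with a trend on gene length and GC content removed, at -0.71 (adjusted p = 0.0093). The gene count includes reads from any edited transcript, so it is no check of the edit, and the libraries are called knockout here by their label.

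The poison exon spans 276 bp in the annotation, from 22258986 to 22259261 on chromosome 16 (GRCm38), and 2 of the 9 annotated Tra2b transcripts contain exactly this exon. Transcripts with it made up 12 ± 1.86% of the Tra2b counts in the libraries labelled naive (SD, n = 8), 6.87 ± 2.03% in the controls (SD, n = 8) and 1.03 ± 0.0156% in the knockout libraries (SD, n = 2). The difference of -5.09 percentage points between control and naive had an exact two-sided permutation p of 0.000466 (adjusted p = 0.000732 over 11 transcript measures, Benjamini-Hochberg). Like the difference in Tra2b level, it cannot be separated from the source of the naive cells. The difference of -5.84 percentage points between knockout and control had an exact p of 0.0222, the smallest that 45 splits can give (adjusted p = 0.0488). The 11 measures overlap, since Tra2b-206 (-5.85 points) and the sums that include it (-5.84 and -5.84) are nearly the same quantity. Their tie at the smallest p lowers the adjusted p, and no adjustment without the overlap was computed. The summed level of the transcripts with the poison exon was 34.3 ± 3.41 CPM in naive, 31.9 ± 10.3 CPM in control and 3.77 ± 0.039 CPM in knockout libraries (SD, n = 8, 8 and 2). The protein-coding transcript Tra2b-204 stood at 241 ± 31, 424 ± 59.2 and 349 ± 8.74 CPM. Tra2b-204 held 83.1 ± 2.25% of the gene's counts in naive, 91.0 ± 2.27% in control and 95.8 ± 0.0403% in knockout libraries (SD). Counts of such overlapping transcripts are estimates, so shares of similar transcripts are uncertain beyond counting error.

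**Figure D1:**
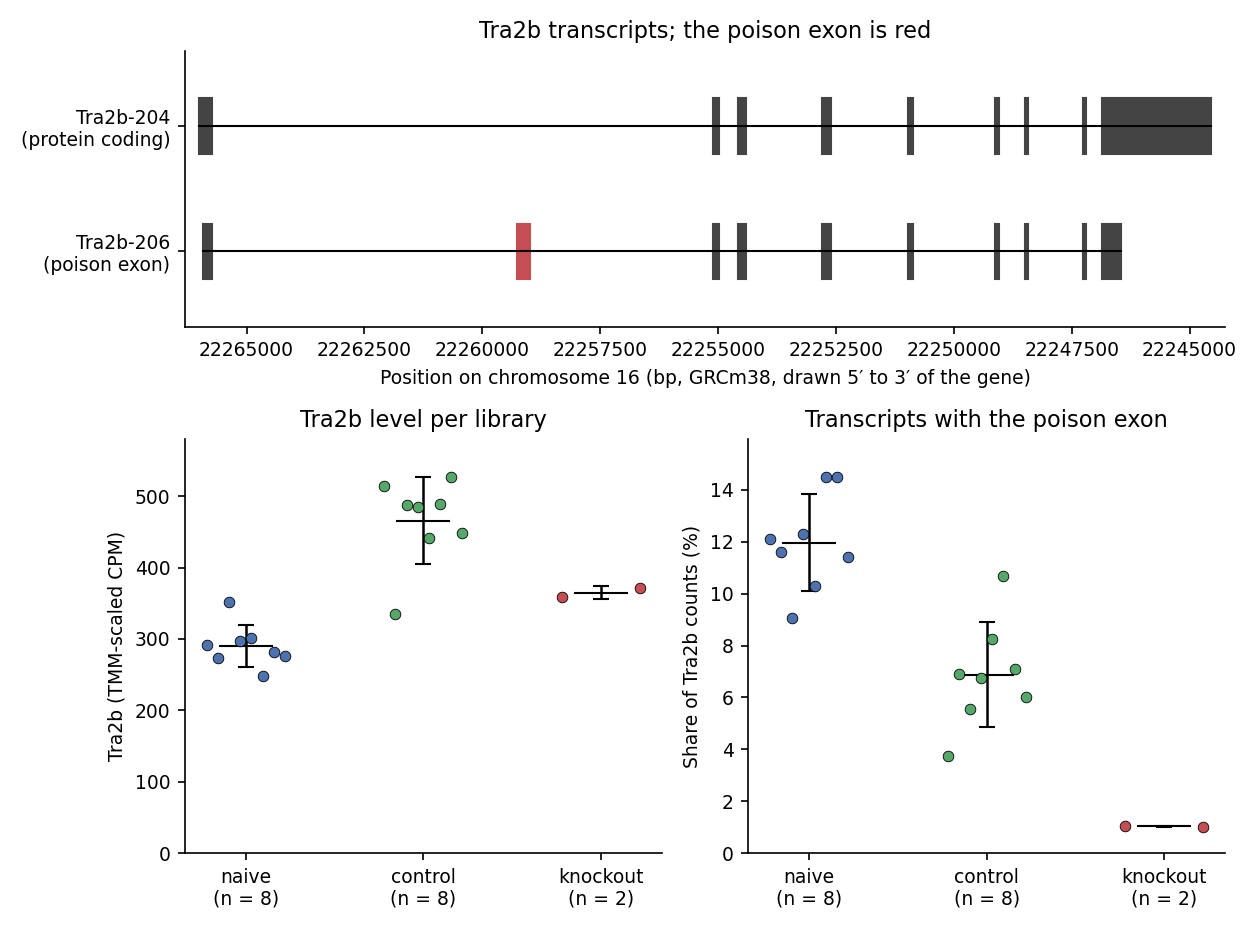
Exons of Tra2b-204 and of Tra2b-206, with the poison exon in red, along chromosome 16 (bp, GRCm38), above the Tra2b level (TMM-scaled CPM) and the percent of Tra2b counts in transcripts with the poison exon, with 1 point per library, the mean and the SD of each group. The poison exon share lies between 9.06 and 14.5% in the libraries labelled naive, between 3.73 and 10.7% in the controls, and at 1.02 and 1.04% in the knockout libraries.

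The libraries differed in receptor segments and in markers of other cells. The OT-I receptor uses the variable segments Trbv12-1 and Trav14. Trbv12-1 held 99.6 to 99.8% of the Trbv counts in the controls and 99.4 and 99.7% in the knockout libraries. In the libraries labelled naive it held 5.95 to 12.4% (exact two-sided permutation p = 0.000155 for control against naive, the smallest that 12870 splits can give, adjusted p = 0.000276 over 48 measures). Trav14 held 97.1 to 98.6% of the Trav counts in the controls and 11.9 to 24.2% in the naive libraries. In each library labelled naive 19 Trbv segments held over 1% of the Trbv counts each, against 1 in each stimulated library. Transcripts of MHC class II, which present peptides to CD4 T cells, were higher in the naive libraries. H2-Ab1 stood at 620 ± 174 CPM, against 33.2 ± 19 CPM in the controls (SD, n = 8 each) and 10.6 ± 1.6 CPM in the knockout libraries (SD, n = 2). Naive libraries 1, 2, 6 and 8 had high X-linked Xist and naive libraries 3, 4, 5 and 7 high Y-linked Ddx3y, with Xist between 0.041 and 128 CPM and Ddx3y between 0.498 and 136 CPM. Every control library held both, at 12.4 to 39.2 and 20.6 to 38.8 CPM. So did knockout 1 (49.5 and 26.5 CPM) and knockout 2 (51 and 32.1 CPM). Whether each stimulated library pools cells of several animals was not tested. The name naive is used here only as the label gives it.

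**Figure D2:**
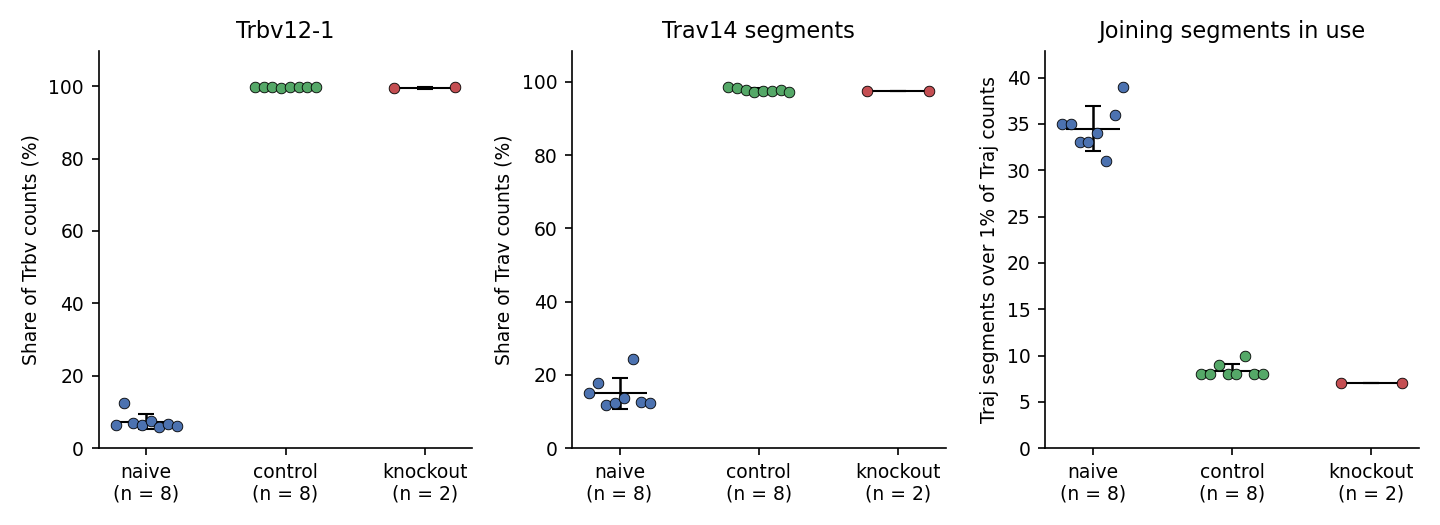
Percent of Trbv counts in Trbv12-1, percent of Trav counts in Trav14 segments, and number of Traj joining segments that each hold over 1% of Traj counts, with 1 point per library, the mean and the SD of each group. The libraries labelled naive lie at 5.95 to 12.4%, 11.9 to 24.2% and 31 to 39 segments, and the controls at 99.6 to 99.8%, 97.1 to 98.6% and 8 to 10 segments.

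The comparison of control with naive asks what differed between these groups. Given the receptor segments, other-cell markers and sex-linked transcripts above, it cannot separate 4 days of peptide and costimulation from the source of the naive cells. Controls had higher transcripts of genes of proliferation, glycolysis and nuclear-encoded oxidative phosphorylation, and lower transcripts of naive and memory genes, interferon-stimulated genes and mitochondrially encoded genes. With an estimated correlation none of these lists passed (adjusted p = 0.389 to 0.564). Among the 8 largest rises of abundant genes were the IL-33 receptor Il1rl1, from 1.22 ± 1.33 to 43.8 ± 7.01 CPM, and the neuropilin Nrp1, from 8.74 ± 1.64 to 204 ± 45.1 CPM (SD, n = 8 each). The inhibitory receptor Pdcd1 went from 37.9 ± 15.1 to 314 ± 27.4 CPM (SD, n = 8 each). The largest falls were in the amino acid transporter Slc6a19, from 53.3 ± 18.8 to 0.174 ± 0.15 CPM, and the phosphodiesterase Pde2a, from 164 ± 47.1 to 1.14 ± 2.44 CPM. The gut-homing receptor Ccr9 fell from 87.8 ± 17 to 0.736 ± 0.464 CPM (SD, n = 8 each). Log2 fold changes were 5.17 (SE 0.52) for Il1rl1, 4.54 (SE 0.16) for Nrp1, 3.05 (SE 0.19) for Pdcd1 and -6.90 (SE 0.34) for Ccr9, with adjusted p of 9.41e-08, 2.01e-13, 2.35e-10 and 1.15e-11 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In all, 12213 of 17078 tested genes differed, 5549 higher and 6664 lower in the controls. The median log2 fold change of all tested genes was -0.09, and -0.18 with libraries scaled to total counts only, where 39.5% of the calls were higher against 45.4%. Among genes with a mean log2 CPM of at least 4 the balance turned, to 3848 higher and 2457 lower, and at 2-fold or more it was 1454 and 3393.

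Cell division genes rose together. All 30 genes of DNA replication and S phase were higher in the controls (camera adjusted p = 3.77e-12; adjusted p = 0.389 with an estimated correlation). The helicase subunit Mcm2 went from 347 ± 53.2 to 768 ± 33.7 CPM and Mcm6 from 649 ± 102 to 1380 ± 37.9 CPM. All 34 genes of mitosis and G2/M phase were higher (adjusted p = 5.44e-13; adjusted p = 0.389 with an estimated correlation), such as the spindle checkpoint kinase Bub1b, from 150 ± 34.1 to 401 ± 22.5 CPM. Of 19 glycolysis genes 17 rose and none fell (adjusted p = 3.39e-06; adjusted p = 0.389 with an estimated correlation), with Eno1 at 1550 ± 182 and 3330 ± 263 CPM and Pkm at 1230 ± 139 and 2500 ± 243 CPM. Of 37 nuclear-encoded genes of oxidative phosphorylation 36 rose (adjusted p = 8.91e-11; adjusted p = 0.389 with an estimated correlation), and Uqcrc1 had a log2 fold change of 0.80 (SE 0.04). Mitochondrially encoded genes went the other way, with 11 of 13 lower (adjusted p = 0.0119; adjusted p = 0.564 with an estimated correlation). Their share of all counts was 1.09 ± 0.0862% in naive and 0.765 ± 0.0471% in control libraries (SD, n = 8 each). Of 25 MYC and ribosome biogenesis genes 19 rose and 1 fell (adjusted p = 0.000465; adjusted p = 0.544 with an estimated correlation). Of 20 cholesterol synthesis genes 15 rose and 1 fell (adjusted p = 0.000246; adjusted p = 0.438 with an estimated correlation). Of 11 heat shock genes 8 rose (adjusted p = 0.0119; adjusted p = 0.544 with an estimated correlation). The amino acid and unfolded protein response list had 18 of 23 genes higher and 3 lower (adjusted p = 0.000241; adjusted p = 0.392 with an estimated correlation). The serine synthesis enzyme Psat1 was up at a log2 fold change of 1.35 (SE 0.09) and the stress factor Ddit3 down at -1.43 (SE 0.10). The SD values of this paragraph have n = 8 in each group.

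Naive and memory genes, interferon-stimulated genes and TCR signalling response genes were mostly lower in the controls. Of 20 naive and memory T cell genes 16 were lower in the controls and 1 higher (camera adjusted p = 4.29e-05; adjusted p = 0.389 with an estimated correlation). The transcription factor Lef1 went from 463 ± 74.6 to 118 ± 10.3 CPM and Bach2 from 39.3 ± 8.24 to 4.24 ± 1.47 CPM (SD, n = 8 each). Of 30 interferon-stimulated genes 29 were lower (adjusted p = 2.36e-07; adjusted p = 0.414 with an estimated correlation). Of 19 TCR signalling response genes 13 were lower and 1 higher (adjusted p = 0.000829; adjusted p = 0.389 with an estimated correlation), the activation marker Cd69 among them at a log2 fold change of -2.57 (SE 0.15). Effector transcription factors had 10 of 15 genes higher and 3 lower (adjusted p = 0.0447; adjusted p = 0.392 with an estimated correlation), and Batf, Tbx21 and Hif1a rose by log2 fold changes of 1.17, 1.17 and 1.08. Of 12 genes of T cell identity 10 fell (adjusted p = 0.000536; adjusted p = 0.389 with an estimated correlation), and Cd8a stood at 1010 ± 73.7 and 455 ± 44.5 CPM. Cytotoxic effector genes did not pass as a list (adjusted p = 0.269), with 4 of 23 higher and 10 lower. The chemokine Ccl5, from 232 ± 85.8 to 6.81 ± 2.21 CPM, and the receptor Klrg1, from 49.1 ± 20.3 to 3.9 ± 2.25 CPM, were among those that fell. The protease Gzmb stood at 297 ± 174 and 274 ± 100 CPM (exact permutation p = 0.776, SD, n = 8 each).

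Splicing regulators moved in part. Of 25 hnRNP and other splicing regulators 19 rose and 4 fell (camera adjusted p = 0.000536; adjusted p = 0.389 with an estimated correlation). Hnrnpll, which controls splicing of the phosphatase CD45, had a log2 fold change of 1.40 (SE 0.08), Hnrnpa1 1.35 (SE 0.10) and Mbnl2 -1.92 (SE 0.14). SR proteins and their kinases split, with 11 of 21 higher and 10 lower (adjusted p = 0.905), a median log2 fold change of 0.24 and a mean of -0.15, and the rotation test fry put the list lower (adjusted p = 0.00735). Srsf3 rose by 0.64 (SE 0.05), and the kinases Clk1 and Srpk1 had log2 fold changes of -1.30 (SE 0.09) and -0.45 (SE 0.04). Genes whose splicing TRA2B controls in other cells had 9 of 11 higher and 1 lower (adjusted p = 0.0135; adjusted p = 0.389 with an estimated correlation), and the histone chaperone Nasp went from 129 ± 21.3 to 277 ± 21.6 CPM (SD, n = 8 each). Nonsense-mediated decay factors had 3 of 14 higher and 4 lower (adjusted p = 0.822), with a median of -0.01 and a mean of 0.01. Of p53 target genes 4 of 20 rose and 9 fell (adjusted p = 0.401), among the latter Sesn1 at -2.24 (SE 0.13) and Trp53inp1 at -2.17 (SE 0.16). The counts of these 3 paragraphs were the same when adjusted over the list alone, except 1 higher and 14 lower for TCR signalling response genes and 9 higher and 2 lower for TRA2B targets. Markers of B, dendritic and NK cells were lower in the controls. All 13 measured B cell genes were lower (adjusted p = 0.000346; adjusted p = 0.389 with an estimated correlation). Of 7 dendritic cell genes 6 were lower and 1 higher (adjusted p = 0.0167; adjusted p = 0.389 with an estimated correlation). All 8 NK cell genes (adjusted p = 0.000829; adjusted p = 0.389 with an estimated correlation) were lower. These counts were the same adjusted over the list alone.

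**Figure D3:**
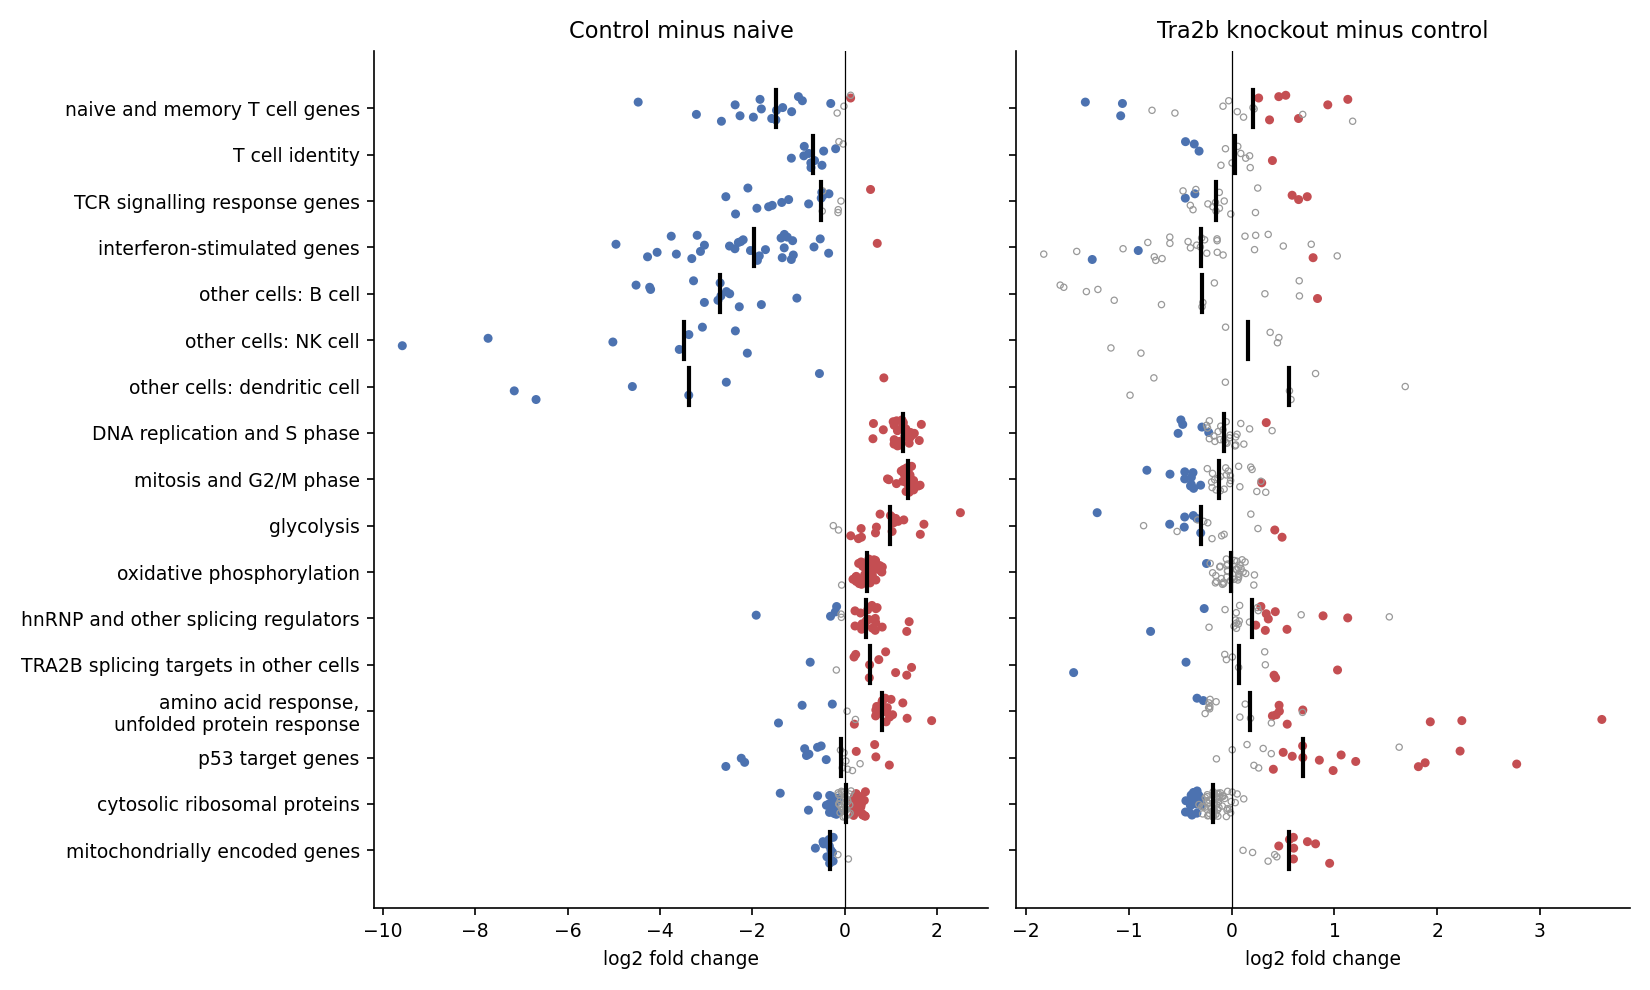
Log2 fold change of each measured gene of 17 lists, for control minus naive and for knockout minus control, with 1 point per gene, filled red (higher) or blue (lower) where it passed the threshold and open where it did not, and a bar at the median. Mitosis genes have a median of 1.38 in the first comparison and -0.12 in the second, and p53 targets -0.07 and 0.69.

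The comparison of knockout with control asks what differed in stimulated cells labelled knockout. The libraries labelled knockout had higher transcripts of p53 target genes (13 of 21; adjusted p = 0.118 with an estimated correlation) and of Asns, Pck2 and Trib3, and lower transcripts of the histone chaperone Nasp, the SR protein kinase Srpk1 and S100a4. The mitochondrial enzyme Pck2 rose from 9.51 ± 1.13 to 47.7 ± 3.54 CPM, the asparagine synthetase Asns from 38.9 ± 11.4 to 184 ± 8.58 CPM and the translation repressor Eif4ebp1 from 14 ± 2.16 to 53.2 ± 1.4 CPM (SD, n = 8 and 2). Their log2 fold changes were 2.33 (SE 0.12), 2.24 (SE 0.22) and 1.93 (SE 0.14), with adjusted p of 2.52e-06, 0.000159 and 1.85e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Nasp fell from 268 ± 19.1 to 92.3 ± 6.62 CPM (log2 fold change -1.54, SE 0.09, adjusted p = 3.11e-06) and Srpk1 from 158 ± 5.73 to 72.7 ± 1.03 CPM (-1.12, SE 0.06, adjusted p = 3.11e-06). The calcium-binding S100a4 fell from 359 ± 81.4 to 81.6 ± 14.6 CPM (-2.14, SE 0.25, adjusted p = 0.000354). The protease Adam8 fell from 64.8 ± 18.2 to 11.6 ± 0.311 CPM (-2.48, SE 0.36, adjusted p = 0.00147). Among abundant genes the interferon-induced Ifitm1 had the largest fall, from 37.9 ± 22.9 to 1.91 ± 0.189 CPM, but did not pass without knockout 1 (adjusted p = 0.0611) or without knockout 2 (adjusted p = 0.132). Tnfrsf25, Il1r2, Fads2 and Utf1 also fell, with log2 fold changes between -3.07 and -1.97. Of 18651 genes tested, 1421 were higher and 1351 lower in the knockout libraries, 51.3% of the calls being higher. That balance moved to 1161 higher and 694 lower with voom (62.6% higher) and to 1459 and 946 without knockout 1 (60.7% higher).

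Of 21 p53 target genes 13 rose and none fell, or 15 adjusted over the list alone (camera adjusted p = 3.34e-08; adjusted p = 0.118 with an estimated correlation). The cyclin Ccng1 went from 156 ± 17.2 to 360 ± 16.4 CPM, Phlda3 from 2.33 ± 0.696 to 16 ± 0.852 CPM and the pro-apoptotic Bbc3 from 1.9 ± 0.54 to 6.70 ± 0.637 CPM (SD, n = 8 and 2). The amino acid and unfolded protein response list had 9 of 23 genes higher and 2 lower, or 11 and 7 adjusted over the list alone, and did not pass (adjusted p = 0.0748). The transcription factor Atf4 rose by a log2 fold change of 0.54 (SE 0.06), and its known targets Chac1 and Trib3 had log2 fold changes of 3.60 (SE 0.36) and 1.93 (SE 0.20). Of cytosolic ribosomal protein genes 15 of 70 were lower and none higher, or 20 lower adjusted over the list alone (adjusted p = 2.86e-07; adjusted p = 0.941 with an estimated correlation), and Rpl13a had a log2 fold change of -0.45 (SE 0.07). Mitosis genes had 10 of 34 lower and 1 higher, or 10 and 2 adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.941 with an estimated correlation). Ect2 had -0.83 (SE 0.12) and Nusap1 -0.60 (SE 0.09). The mitosis list did not pass without knockout 1, where its median log2 fold change was -0.14 against -0.12 with both. With the trend on gene length and GC content removed its median was -0.28 (camera adjusted p = 6.3e-08). Glycolysis genes had 7 of 19 lower and 2 higher, or 11 and 3 adjusted over the list alone (adjusted p = 0.0236; adjusted p = 0.941 with an estimated correlation). That list did not pass without knockout 1 (adjusted p = 0.0748), without knockout 2 (adjusted p = 0.0602) or with the trend on gene length and GC content removed (adjusted p = 0.0767), where its median log2 fold change was -0.32 against -0.30 with the trend kept.

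Among splicing factors, hnRNP and other splicing regulators had 9 of 26 genes higher and 2 lower, or 11 and 2 adjusted over the list alone (adjusted p = 0.0119; adjusted p = 0.941 with an estimated correlation). Hnrnpa2b1 and Ptbp1 had log2 fold changes of 0.33 (SE 0.05) and 0.36 (SE 0.06), and Hnrnpa1 had -0.79 (SE 0.13). Without knockout 2 that list had an adjusted p of 0.108, and with the length and GC trend removed its median log2 fold change was -0.04 (adjusted p = 0.906). SR proteins and their kinases had 4 of 21 higher and 2 lower, or 5 and 2 adjusted over the list alone. That list did not pass (camera adjusted p = 0.888, median -0.02 with the test pointing up). Tra2a, the paralog of Tra2b, had a log2 fold change of 0.43 (SE 0.11). The higher calls of Tra2a, Hnrnpa2b1 and Ptbp1 were lost without knockout 2. The TRA2B targets had 3 of 11 higher and 2 lower both over all genes and adjusted over the list alone (adjusted p = 0.888), and nonsense-mediated decay factors had 2 higher and 2 lower of 14 in both counts (adjusted p = 0.895, median -0.01, mean 0.09). Mitochondrially encoded genes had 8 of 13 higher, or 11 adjusted over the list alone (adjusted p = 0.000452; adjusted p = 0.941 with an estimated correlation). Red blood cell genes had 6 of 7 higher in both counts (adjusted p = 0.0119; adjusted p = 0.941 with an estimated correlation). Both rested on knockout 1, without which the adjusted p were 0.639 and 0.44. That library held 1.53% mitochondrially encoded counts and 39.4 CPM of the haemoglobin gene Hbb-bs, against 0.859% and 4.19 CPM in knockout 2 and at most 0.834% and 5.46 CPM in the controls.

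T cell genes moved in both directions in the knockout libraries. Naive and memory genes had 7 of 20 higher and 3 lower, or 9 and 4 adjusted over the list alone (adjusted p = 0.191), with Nsg2 at a log2 fold change of 1.13 (SE 0.17) and the IL-7 receptor Il7r at -1.08 (SE 0.22). Effector transcription factors had 2 of 15 higher and 3 lower in both counts (adjusted p = 0.884), with Irf4 at 0.96 (SE 0.16; 0.41 without knockout 2, adjusted p = 0.0876), Tbx21 at -0.50 (SE 0.10) and Id2 at -1.07 (SE 0.21). Inhibitory receptors had 5 of 16 higher and 1 lower, in the same numbers adjusted over the list alone (adjusted p = 0.0748). Tigit went from 6.27 ± 2.11 to 20.5 ± 1.74 CPM and Cd160 from 143 ± 11.9 to 104 ± 6.97 CPM (SD, n = 8 and 2). Without knockout 2, Il7r, Tbx21, Id2 and Cd160 kept their direction and did not pass (adjusted p = 0.124, 0.0716, 0.123 and 0.111). Cytotoxic effector genes had 2 of 23 higher and 2 lower, or 7 and 3 adjusted over the list alone (adjusted p = 0.46). DNA replication genes had 1 of 30 higher and 5 lower, or 1 and 6 adjusted over the list alone (adjusted p = 0.0748), with Rrm2 at -0.52 (SE 0.07). With the length and GC trend removed, an alternative chosen after seeing the data, that list passed (camera adjusted p = 0.0153). Its median log2 fold change was then -0.17, against -0.08 with the trend kept. Interferon-stimulated genes had 1 of 30 higher and 2 lower in both counts (adjusted p = 0.329). Oxidative phosphorylation had none of 37 higher and 1 lower, or none adjusted over the list alone (adjusted p = 0.884), and cholesterol synthesis 1 of 20 lower in both counts (adjusted p = 0.415).

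The calls depended on knockout 2: without it 651 genes were called, against 2405 without knockout 1, and the abundant Usp9x (38.9 CPM in knockout 1, 189 in knockout 2) and Ranbp2 (82.7 and 307) rose only with it. Removing the trend on gene length and GC content, an alternative chosen after seeing the data, left 796 higher and 1773 lower calls, 31.0% of them higher. Of 112 named genes past the threshold 25 kept their call without either knockout library and without that trend, among them Pck2, Asns, Eif4ebp1, Chac1, Trib3, Ccng1, Phlda3, Bbc3, Nasp, Srpk1, S100a4, Adam8 and Tigit.

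**Figure D4:**
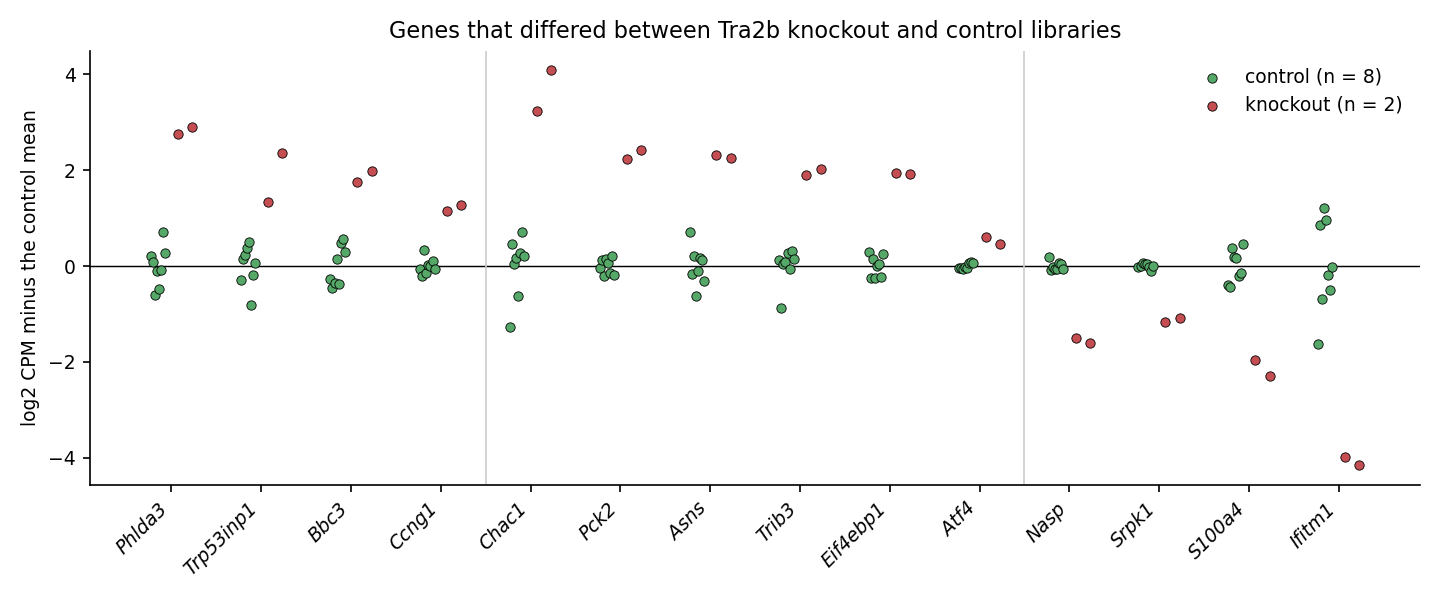
Log2 CPM minus the control mean for named genes in each control (green) and knockout (red) library, with 1 point per library. Both knockout libraries lie above every control for Pck2, at 45.2 and 50.2 CPM, and below every control for Nasp, at 87.6 and 97 CPM.

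Against the libraries labelled naive, the knockout libraries had 4177 of 19776 tested genes higher and 4660 lower, and Tra2b had a log2 fold change of 0.37 (SE 0.10, adjusted p = 0.009, edgeR's quasi-likelihood test). Of 30 DNA replication genes 30 rose in both counts (camera adjusted p = 2.94e-11; adjusted p = 0.364 with an estimated correlation). Of 34 mitosis genes 33 rose, or 34 adjusted over the list alone (adjusted p = 2.94e-11; adjusted p = 0.375 with an estimated correlation). Of 20 naive and memory genes 16 fell and 2 rose in both counts (adjusted p = 2.4e-05; adjusted p = 0.364 with an estimated correlation). Of 20 p53 targets, of which 4 were higher and 9 lower in the controls, 12 rose and 3 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.364 with an estimated correlation). The Tra2b call did not pass without knockout 1 (adjusted p = 0.0626) or without knockout 2 (adjusted p = 0.0561).

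Whether genes that differed between control and naive libraries differed the other way in the knockout libraries was asked across genes, which are not independent replicates. Stimulation and the source of the naive cells were not separated. Of 16761 genes tested in both comparisons 2170 were called in both, and 1621 of these, 74.7%, had opposite signs. There were 855 higher in the controls and lower in the knockout libraries, and 766 the other way. The same controls entered both lists, which favours opposite signs, and no count for unchanged groups was computed. The correlation of the 2 changes over 20750 genes had a median Pearson r of -0.231 (range -0.281 to -0.176) and a median Spearman rho of -0.254, with the controls split 4 and 4 between the changes in 70 ways. With all controls in both changes r was -0.302. In 200 simulations of unchanged groups r was -0.315, a value set by the group sizes alone, so these r cannot be compared. The covariance was -0.332, against -0.063 in those simulations. Without knockout 1 the median r was -0.167.

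**Figure D5:**
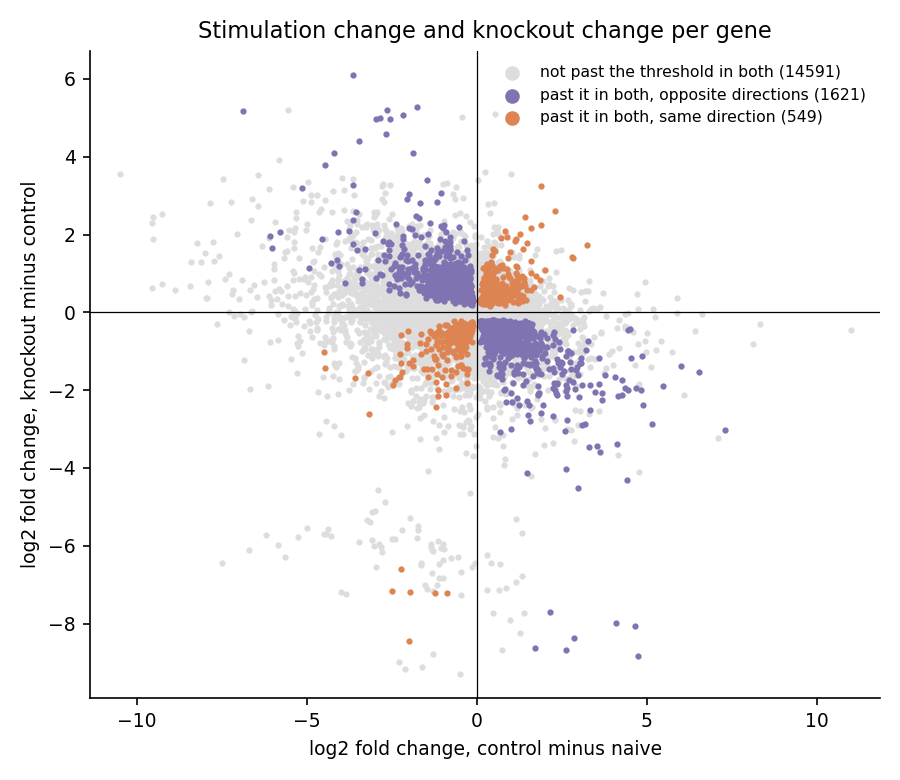
Log2 fold change of knockout minus control against that of control minus naive, with 1 point per gene tested in both comparisons, purple where it passed both thresholds in opposite directions and orange where it passed both in the same direction. Of the 2170 coloured genes, 1621 are purple and 549 orange.

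Transcript usage, the split of a gene's counts among its transcripts, was tested because Tra2b encodes a splicing factor. Between control and naive libraries it differed in 3857 of 8581 genes (diffSpliceDGE with a Simes test per gene, Benjamini-Hochberg), Tra2b among them (adjusted p = 5.31e-11). A quasi-likelihood fit, chosen after seeing the data, passed 751 genes, 714 of them shared. Its relative Tra2a had a retained-intron transcript, Tra2a-203, at 33.7 ± 3.13% of its counts in naive and 12.4 ± 1.68% in control libraries (SD, n = 8 each, gene adjusted p = 3.26e-15). In Rabgap1l the share of a transcript annotated for nonsense-mediated decay, Rabgap1l-205, went from 28.6 ± 1.62 to 8.27 ± 1.34% (SD, n = 8 each, gene adjusted p = 6.65e-22). The smallest adjusted p was that of Relb, where the retained-intron transcript Relb-206 held 12.4 ± 2.91% in naive libraries and 0 counts in every control library, which allows at most 0.204% (3 counts, counting error only). Of the TRA2B targets Nasp, Chek1, Smn1, Anxa6 and Fancm also passed, and Ktn1 (adjusted p = 0.142) and Homer1 (adjusted p = 0.508) did not.

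Between knockout and control, transcript usage differed in 308 of 9653 genes by the same test. Tra2b passed (adjusted p = 4.57e-05). Tra2b-206, which carries the poison exon, had a log2 change of -2.74 relative to the gene (adjusted p = 2.59e-05). The listed TRA2B targets Nasp (adjusted p = 0.00386), Ktn1 (adjusted p = 0.000361) and Rabgap1l (adjusted p = 5.54e-05) also passed. Tra2a (adjusted p = 0.0549), Smn1 (adjusted p = 0.0804) and Chek1 (adjusted p = 0.288) did not pass, nor did Hipk3, Sgo2a, Homer1, Anxa6 and Fancm. The smallest adjusted p were those of Flna, Ppia and Ergic2. For Flna another split of the libraries also gave a small unadjusted p (1.8e-54 against 2.4e-83), while the smallest from another split was 0.462 for Ppia and 0.0113 for Ergic2. Among the listed targets that passed, the smallest unadjusted p from another split was 3.88e-05 for Ktn1 (4e-06 in the real one), 0.0781 for Nasp and 0.0117 for Rabgap1l. Transcripts with at least 100 counts in each library of one group and 0 in the other numbered 19, against 6 to 22 when pairs of controls were set against the other controls. In data simulated for this comparison the test recovered 3.5% of genes with a 4-fold change in a transcript of at least 1 CPM, with 29 false calls, and 86.5% with a 16-fold change in one of at least 16 CPM, with 59. With a quasi-likelihood fit in its place, chosen after seeing the data, 164 genes passed, 91 of them shared, and Tra2b (adjusted p = 0.19), Nasp (adjusted p = 0.692), Ktn1 (adjusted p = 0.424) and Rabgap1l (adjusted p = 0.415) did not.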

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

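The tests of shared reads between V segments, of swapped labels, of dendritic cells, of a batch shared by the libraries numbered 1 and 2, and of other splits for knockout lists and knockout transcript usage were chosen only after the result was seen. A library far from its group by Dixon's criterion was found in 31 of 280 groups of 8 values, where chance gives about 1 in 20.

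The libraries labelled naive held many receptor segments, with 7.33 ± 2.11% of Trbv counts in Trbv12-1 (SD, n = 8). Reads shared between near-identical V segments do not explain this, since at least 74.5% of the Trbv counts in each naive library lay outside Trbv12-1 and Trbv12-2. Labels swapped with the stimulated groups are argued against by the lowest Trbv12-1 share of 99.4% among control and knockout libraries, which leaves no partner out of place. T cells without the OT-I receptor may account for it: each naive library held at least 31 Traj segments above 1% of the Traj counts, against 8 to 10 in the controls. A sample from outside the study, or cells of another genotype, stays open and was not tested.

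Transcripts of MHC class II stood at 620 ± 174 CPM for H2-Ab1 in the libraries labelled naive and 33.2 ± 19 CPM in the controls (SD, n = 8 each). The scaling of the libraries is argued against by a fold of 19.9 on total counts alone. Conventional dendritic cells may contribute: over the 8 naive libraries H2-Ab1 rose with the sum of Flt3, Xcr1 and Clec9a (Pearson r = 0.949, exact two-sided permutation p = 0.00186). Spearman's rho was 0.952 (exact permutation p = 0.00114), and r was 0.731 without the 2 farthest libraries, with 1 relation tested. The naive libraries fall 4 and 4 by sex-linked transcripts, and within each set the libraries had the same rank order for H2-Ab1 and for the dendritic sum, with no correlation computed. B cells as a source stay open and were not analysed here.

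For the genes called between knockout and control, chance is argued against, at the smallest permutation p that 45 splits can give (0.0222). There were 2772 genes called, and at most 3 in the other 44 splits (1 of 45 splits as large). Those splits mix knockout and control libraries, which widens the spread within groups, so 3 is no estimate of the false calls. A batch shared by the libraries numbered 1 and 2 is argued against as the whole cause by the 2762 genes called against controls 3 to 8 alone. Their median change against controls 1 and 2, which had no part in that selection, was 0.579, and 0.671 against controls 3 to 8, a ratio of 0.862, where such a batch would bring it near 0. Against controls 1 and 2 alone 5 genes passed (2811 unadjusted), and 0 with the replicate number as a block (3536 unadjusted), so the calls themselves were not repeated within those libraries. Gene length or GC content is argued against as the whole cause, since 66.1% of the called genes kept their call and direction with the trend removed. This held for 719 of the 1421 higher calls, 50.6%, and for 1114 of the 1351 lower calls, 82.5%, so a length or GC trend may account for part of the higher calls. Preparation of the knockout libraries apart from the controls stays open and was not tested.

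Chance is also argued against for the number of knockout transcript usage calls, with 308 genes, a highest other of 120 and a median of the others of 80 (1 of 45 splits as large). There too the other splits mixed the groups, and 29.8% of the 406 called transcripts were at 0 in a group. Every other split still passed at least 47 genes, so part of the 308 may be false calls, in a number not estimated. Chance is argued against as well for control against naive genes (12213, highest other 9061, a split that kept 7 controls together, 1 of 100 splits). The same holds for control against naive transcript usage (3857, highest other 1463; 1 of 100 splits). It cannot be excluded for the number of gene lists called, with 7 against a highest other of 17 for knockout against control (22 of 45 splits as large) and 19 against 21 for control against naive (9 of 100 splits as large). Of the 7 knockout lists, p53 targets had the smallest camera p of the 45 splits. With the real one included, as small a p was given by 3 splits for hnRNP regulators, 9 for mitochondrially encoded genes, 10 for mitosis, 11 for red blood cell genes, 12 for ribosomal proteins and 15 for glycolysis. Of the 19 lists for control against naive, 4 had the smallest camera p of the 100 splits: naive and memory genes, DNA replication, glycolysis and T cell identity. As small a p was given by 2 splits for hnRNP regulators, 3 for TRA2B targets, 4 for NK cells, 6 for mitosis, 7 for the amino acid response, 7 for dendritic cells, 10 for interferon-stimulated genes and 10 for oxidative phosphorylation. It was given by 14 for TCR response genes, 15 for effector transcription factors, 19 for B cells, 21 for cholesterol synthesis, 31 for mitochondrially encoded genes, 32 for heat shock genes and 37 for MYC genes. The median change of each of the 19 was larger than in every other split. Mixing the groups shrinks any real difference, so this adds nothing about the lists as sets.

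Naive library 2 lay apart for the mitochondrially encoded share (0.898%, others 1.06 to 1.17%), the Trbv12-1 share (12.4%, others 5.95 to 7.53%) and the Tra2b-207 share (0.0383%, others 0). It also lay apart for Il1rl1 (4.18 CPM, others 0 to 1.5), Nrp1 (12.1 CPM, others 6.67 to 8.88), S100a4 (47.2 CPM, others 11.9 to 24.9), Tbx21 (218 CPM, others 108 to 160) and Itgae (82.2 CPM, others 122 to 142). Other naive libraries lay apart for Trav14 (24.2% in naive 6, others 11.9 to 17.7%), Hbb-bs (11.2 CPM in naive 8, others 0.629 to 4.98) and Pde2a (273 CPM in naive 5, others 112 to 177). The same held for the Tra2b-201 share (1.3% in naive 1, others 0.516 to 0.866%) and the Tra2b-208 share (3.43% in naive 6, others 1.99 to 2.63%).

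Control 1 lay apart for Pde2a (6.92 CPM, others 0.0222 to 0.737), Slc16a5 (2.24 CPM, others 0.419 to 0.76) and Nasp (316 CPM, others 259 to 286). It also lay apart for Adam8 (26.3 CPM, others 56.6 to 83.1), Tigit (11.3 CPM, others 4.59 to 7.2) and Cxcr5 (14.1 CPM, others 2.32 to 5.35). Control 2 lay apart for Tra2b (335 CPM, others 441 to 527), Trib3 (2.05 CPM, others 3.6 to 4.67) and the Tra2b-209 share (0.0199%, others 0.00291 to 0.0101%). Control 4 lay apart for Apol7c (1.6 CPM, others 0.173 to 0.578), Ddit3 (10.4 CPM, others 6.32 to 7.8) and Alas2 (0.305 CPM, others 0 to 0.0266). Further values were Bach2 (7.78 CPM, others 2.86 to 4.38) and Itgae (8.66 CPM, others 0.877 to 3.3) in control 5. There were also Bub1b (455 CPM, others 369 to 407) and Klra9 (0.0741 CPM, others 0) in control 3, with Flt3 (0.561 CPM, others 0.0423 to 0.216) and the Tra2b-207 share (0.0553%, others 0) in control 8.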

How the results depend on the processing

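The tests with controls 1 and 2 or 3 to 8 alone, without the length and GC trend, without receptor segments and other-cell lists, and with quasi-likelihood transcript usage were chosen only after the result was seen. The counts of called genes stayed within 1.5 times their value, with Tra2b on the same side of the threshold, for DESeq2, RLE factors, total counts, no low-count filter, 1 fit of all groups, voom and thinned libraries. The share of higher calls moved in these from 39.5 to 46.6% for control against naive, 51.0 to 62.6% (voom, 694 lower in place of 1351) for knockout against control and 38.6 to 54.8% for knockout against naive. An added 2-fold threshold left 4847, 703 and 4095 genes for control against naive, knockout against control and knockout against naive, by construction. Testing only genes of log2 CPM 4 or more called 6305 genes in the first (6047 shared, 61.0% higher against 45.4%) and 5105 in the last (4927 shared, 58.4% higher against 47.3%), with fewer genes tested. With the replicate number as a block, 0 genes were called by edgeR between knockout and control (3536 unadjusted; 1 residual degree of freedom) and 3322 between knockout and naive, where Tra2b had 0.41 (adjusted p = 0.0899). Against controls 1 and 2 alone 5 genes were called (2811 unadjusted), with fewer samples. Tra2b between knockout and control passed against controls 3 to 8 (-0.37, adjusted p = 0.00901) and with the trend removed (-0.71, adjusted p = 0.0093); the cause was not tested. No list passed with an estimated correlation (0, 0 and 0), and fry, which asks another question, passed 31 lists for control against naive. SR proteins turned lower with fry (adjusted p = 0.00735 for control against naive and 0.0313 for knockout against naive). The reversal was -0.302 with all controls in both differences. The -0.315 of simulated unchanged groups is set by the group sizes alone and cannot be compared with that value. At log2 CPM 4 or more the reversal was -0.313, and the cause was not tested. Usage calls were 751 for control against naive with quasi-likelihood, and 882 with voom, 1713 with the block and 164 with quasi-likelihood for knockout against control, of which 164, 188 and 91 were among the 308; the cause was not tested. Leaving out 1 library gave 11976 to 12243 genes for control against naive, 651 (without knockout 2) to 2858 for knockout against control and 6766 to 8986 for knockout against naive. Tra2b was at 0.68 to 0.77, -0.40 (without control 2, adjusted p = 0.00803) to -0.31, and 0.31 to 0.41 (not past the threshold without knockout 1 or without knockout 2, adjusted p = 0.0626 and 0.0561). There were 5 and 5 lists for knockout against control, 19 and 19 for knockout against naive, a reversal of -0.211 to -0.167 (without knockout 1) and 406 to 436 usage calls, 125 and 129 of them among the 308. A lone knockout library was assumed to vary like the controls. Among named values, 4032 kept their direction and side for control against naive and 7 became stronger; for knockout against control 2909 kept them, 48 became stronger and 447 weaker. In simulated data a 4-fold change in a transcript of at least 1 CPM was recovered in 3.5% of cases for knockout against control and in 64.5% for control against naive. For transcripts of at least 16 CPM the knockout value was 16.5%, so depth alone was not the limit.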

Other observations

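None of the tests of hypotheses here was chosen only after the result was seen.

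Further lists between control and naive did not pass. Inhibitory receptors had 5 of 16 genes higher and 7 lower (camera adjusted p = 0.905, median -0.23 with the test pointing up), cytokine and costimulatory receptors 8 of 21 higher and 12 lower (adjusted p = 0.301), and homing receptors 6 of 17 higher and 8 lower (adjusted p = 0.843). Lag3 had a log2 fold change of 2.49, Il6st -2.72, Itgb1 1.96 and Itgae -5.29. Pro-apoptotic genes had 8 of 14 higher and 3 lower (adjusted p = 0.269), anti-apoptotic genes 4 of 10 in each direction (adjusted p = 0.905) and ribosomal proteins 24 of 70 higher and 16 lower (adjusted p = 0.419). Among markers of other cells, plasma cells had 1 of 5 higher and 3 lower (adjusted p = 0.551), macrophages 6 of 11 lower (adjusted p = 0.231), neutrophils 5 of 6 lower (adjusted p = 0.17), CD4 T cells 3 of 7 in each direction (adjusted p = 0.687) and red blood cells 1 of 5 lower (adjusted p = 0.624). Sex-linked genes had none past the threshold (adjusted p = 0.461, median -0.48 with the test pointing up), and platelet and stroma genes were too few to test. The counts were the same adjusted over the list alone except homing receptors (6 and 9), macrophages (5 lower) and neutrophils (6 lower).

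Between knockout and control, cytokine and costimulatory receptors had 5 of 21 higher and 2 lower (adjusted p = 0.488), homing receptors 3 of 17 in each direction (adjusted p = 0.885, median 0.09, mean -0.04) and TCR signalling response genes 3 of 19 higher and 2 lower (adjusted p = 0.888). Il21r had a log2 fold change of 0.68, Cxcr6 -1.48 and Myc -0.45. Pro-apoptotic genes had 2 of 14 higher and 3 lower (adjusted p = 0.0755), anti-apoptotic genes 3 of 10 lower (adjusted p = 0.508), MYC and ribosome biogenesis genes 5 of 25 lower (adjusted p = 0.0793) and heat shock genes none of 12 (adjusted p = 0.666). T cell identity had 1 of 12 higher and 3 lower (adjusted p = 0.885, median 0.03, mean -0.02) and sex-linked genes 1 of 6 higher, Xist (adjusted p = 0.952, median -0.16, mean 0.06). Of other cells, B cell markers had 1 of 13 higher (adjusted p = 0.885) and CD4 T cell markers 1 of 7 higher and 2 lower (adjusted p = 0.52). No member passed for plasma cells (adjusted p = 0.806), macrophages (0.806, median -0.01, mean 0.19), neutrophils (0.0502), dendritic cells (0.884), NK cells (0.888, median 0.16, mean -0.14), platelets (0.895) or stroma (0.488). With the length and GC trend removed the neutrophil list passed (camera adjusted p = 0.0148). Its median log2 fold change was then 2.26, against 2.25 with the trend kept. Adjusted over the list alone the counts differed for pro-apoptotic (2 and 4), anti-apoptotic (1 and 3), MYC (1 and 7) and B cell genes (1 and 4).

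A wider response of the transcription factor ATF4 was a hypothesis for the amino acid response genes of the knockout libraries, which would raise the aminoacyl-tRNA synthetases. A list of 12 synthetase genes gave a camera p of 0.149 (0.594 with an estimated correlation), and 21 of 45 splits gave a p as small. Nars, Tars, Aars and Mars were higher and Lars lower, so these data decide neither way.

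A change in which Nasp transcript is made was a hypothesis for the lower Nasp count. Nasp-205 had a log2 change of 0.40, against -0.58 for Nasp-203, -1.70 for Nasp-202 and -2.97 for Nasp-201. The transcripts did not move alike, so altered processing of Nasp may contribute, but Nasp-205 stood at 2.02 CPM in the knockout libraries, and the usage call of Nasp was lost without either knockout library (adjusted p = 0.111 and 0.232).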
